A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

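Chromatin immunoprecipitation of Swr1, the ATPase of the SWR1 complex that places the histone variant H2A.Z in yeast chromatin, was measured on 8 two-colour tiling arrays. Swr1 carried a TAP tag, which binds IgG and was pulled down on IgG-coupled beads. Each of 4 *Saccharomyces cerevisiae* genotypes had 2 arrays: wild type (WT), a strain lacking Swc2 (a SWR1 subunit), a strain lacking Htz1 (the yeast H2A.Z), and the double mutant. Per the labels' protocols, strains were grown in 200 mL of rich medium at 25 °C to an A600 of 0.8. Sheared chromatin was immunoprecipitated, the DNA was amplified by ligation-mediated PCR, and fragments of 75 to 300 bp were taken. A further 15 cycles incorporated amino-allyl dUTP, to which Cy3 or Cy5 was coupled. On replicate 1 of each genotype the labels put the immunoprecipitated (IP) DNA in Cy5 and genomic input DNA in Cy3, and replicate 2 was the dye swap. The 4 arrays of replicate 1 formed 1 slide and the 4 dye swaps the other. Nothing in the labels gave more than 1 immunoprecipitation per genotype, so the 2 arrays were treated as 1 sample measured on 2 occasions.

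The deposited scanner files held spot intensity values that Agilent Feature Extraction 10.10.1.1 had computed, per the file headers. The processed signal in each channel was background-subtracted and dye-normalized with a linear factor, per the file headers, which listed a lowess factor of 0. The deposited log10 ratio of Cy5 over Cy3 equalled that of the processed signals on 99.2 to 99.5% of features, to within 0.0001. The deposited value table of the whole series held log2 values of Cy3 over Cy5, uncentred and with no sign change on swapped arrays. That table's columns did not hold the arrays they were named for, as given in the results. Median and background intensity values deposited in the scanner files were used for 1 alternative. The build named in the headers was sacCer1. No aligner applied to these arrays, and the deposited files paired probes with neither positions, sequences nor gene names.

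All 180880 features were read, and 3440 control features were left out. The remaining 177440 features held 167240 different probes, of which 10200 were printed on 2 features. Features marked as non-uniform or population outliers in either channel were dropped array by array. The main quantity was log2 of the IP over the input processed signal with the IP as numerator on every array, centred on each array's median, with no loess or quantile step. Spots of 1 probe were averaged.

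The design fixed before the data were examined summarised probes over promoters, and this could not be done without probe positions. Tiles of 20 consecutive probe serial numbers took the place of promoters, a size chosen after seeing that values of neighbouring serial numbers were correlated. A tile needed 3 probes or more, and its value was their mean. All thresholds stayed as designed. A tile was called bound at 1.5-fold or more above the array median on both arrays. It was called lower or higher in a comparison when the change was at least 1.5-fold on both dye orientations. Changes were taken within a slide and then averaged over the 2 slides. Results that needed start codons, the loci of *SWC2* and *HTZ1*, chromosomes, promoter classes or the 16 gene lists fixed in the design were therefore not obtained as designed. The rule for named features had been the lowest changes among features bound in the comparator and the highest among those bound in the mutant. It was applied to tiles, and 2 that were lower and 2 that were higher are given by the ID of their first serial number. No p-value is given, because each genotype was 1 sample. Technical spread, where given, is shown as the values of both slides.

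Changes against the same WT arrays were simulated 100 times with unchanged groups. One simulation used the spread between dye orientations alone, and another took the spread between genotypes as noise. The calling steps were tested on simulated data for the comparison of swc2∆ with WT, with 200 of the 4378 tiles changed. Of 100 tiles changed 2-fold, 89 were called on both orientations, and limma called 99. At 3-fold, 100 of 100 were called by both. Among 4178 unchanged tiles, 1 was called on both orientations and 8 were called by limma. The noise simulated there was that between dye orientations, not that between preparations.

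Alternatives covered background correction, loess, quantile and SD scaling, the value table, dim probes, probe summaries, thresholds, omission of either slide, the choice of bound tiles and a limma fit. Normexp used median rather than mean foreground signals. For the value table, outlier marks were those of the scanner file of the sample each column named, which was another array than its values came from. Tile sizes of 10 and 40, exchanged dyes, and exchanged dyes with the value table's genotypes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. A table of gene positions of assembly R64 served only for the closing hypothesis, and none of its coordinates are printed because the builds differ. Array precision is limited by the number of arrays, 2 per genotype.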

Results

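Swr1-TAP occupancy was compared between WT, swc2∆, htz1∆ and swc2∆ htz1∆ yeast to ask how far a SWR1 subunit and the complex's own product, H2A.Z, govern where SWR1 sits on chromatin. Swc2 binds DNA and H2A.Z within the complex. The measurement was the log2 ratio of IP over genomic input DNA on custom tiling arrays, with 2 arrays of opposite dye per genotype. Probes carried serial numbers from 1008778 to 2154206 in 22 runs, and 83620 serial numbers had probes, most of them on both strands. The longest run spanned 30972 serial numbers and the next 26507, whereas the other runs spanned 5115 or fewer. Probe names began with CHG at 78149 serial numbers and with CEN at 5471. Tiles of 20 serial numbers numbered 4378, of which 4088 were CHG and 290 CEN tiles. Positions and gene names were not given for the probes, so tiles and runs are described in place of genes.

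Signal was well above background on 98.4 to 98.8% of features in Cy3 and 98.1 to 98.8% in Cy5. No feature was saturated on any array. Median processed signals were 1450 to 1826 in the channel labelled IP and 1693 to 1905 in the channel labelled input, against median local backgrounds of 51 to 57 in Cy3 and 39 to 43 in Cy5. Outlier marks removed 7.10 to 16.8% of features on the first slide and 1.09 to 3.53% on the dye-swap slide. Values of the probe strands at 1 serial number correlated with r from 0.886 to 0.971. Along the array, IP/input values 1 serial number apart correlated with r from 0.930 to 0.977. The correlation fell to between 0.452 and 0.557 at 10 serial numbers and to between 0.0884 and 0.204 at 20.

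The genotype of each array rested on the labels of the scanner files. All 8 columns of the deposited value table equalled the scanner ratios of a different sample than the one named, with a largest difference of 5.0e-06 log2 units. The columns named WT held the scanner values labelled swc2∆ htz1∆ and the reverse, and those named swc2∆ held the values labelled htz1∆ and the reverse. Dye orientation matched in every column. Column medians ran from -0.24 to 0.083, and each column correlated with its own sample's scanner file with r of only 0.174 to 0.306. The deleted genes are the usual check of such labels, but their probes could not be located. No stretch of 25 serial numbers was lost in some genotypes alone at the depth of the stretches lost in all. Across the 14 ways of parting the genotypes, the largest such loss was 1.23 to 2.62 on the log2 scale. A genotype below therefore means the arrays labelled with it in the scanner files, and directions and bound sets depend on that assignment and on the dyes the labels give.

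In the arrays labelled WT, 991 of 4378 tiles were bound, or 22.6%. These tiles formed 654 groups of adjacent tiles, with a median of 1 tile and at most 6, or at most 8 with the ratio turned to input over IP. The SD over WT tiles was 0.84. The highest bound WT tile, CHG_P01125060, stood at 3.18 on the first slide and 4.07 on the dye swap. The same tile was also high in swc2∆ at 3.33 and htz1∆ at 3.10, and stood at 1.096 in the double mutant. With the ratio turned these values change sign, and the tile would not be bound. The mutants had like numbers of bound tiles: 1049 in swc2∆ (24.0%), 1092 in htz1∆ (24.9%) and 987 in swc2∆ htz1∆ (22.5%). Bound is relative to each array's own median, so like counts cannot show whether total binding changed. With the ratio turned, 17.6% of tiles would be bound in WT, 20.4% in swc2∆, 18.4% in htz1∆ and 18.3% in the double mutant, so that swc2∆ rather than htz1∆ would have the most. The longest stretch of adjacent bound tiles was 12 tiles in swc2∆, 9 in htz1∆ and 6 in the double mutant, and with the ratio turned it was 9, 8 and 7 tiles. Each genotype was 1 immunoprecipitation, so none of these counts has a replicate check.

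Bound tiles were mostly not shared between genotypes. WT and swc2∆ shared 361 bound tiles where independent sets would share 237. WT and htz1∆ shared 393, against 247 for independent sets, and WT and the double mutant shared 306, against 223. Bound in all 4 genotypes were 85 tiles, where independent sets would give 13.4, and 2550 tiles were bound in at least 1. With the ratio turned, WT would share 215 bound tiles with swc2∆, 201 with htz1∆ and 189 with the double mutant, where independent sets would share 157, 142 and 141. Bound in all 4 would be 26 tiles, against 5.29, and 2199 in at least 1. Across tiles, IP/input values of different genotypes correlated with Pearson r from 0.201 to 0.298 and Spearman rho from 0.186 to 0.277. The lowest Pearson r was between WT and the double mutant and the highest between swc2∆ and the double mutant. Between the dye orientations of 1 genotype, r was 0.964 to 0.971. Tiles within an array are not independent replicates.

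**Figure D1:**
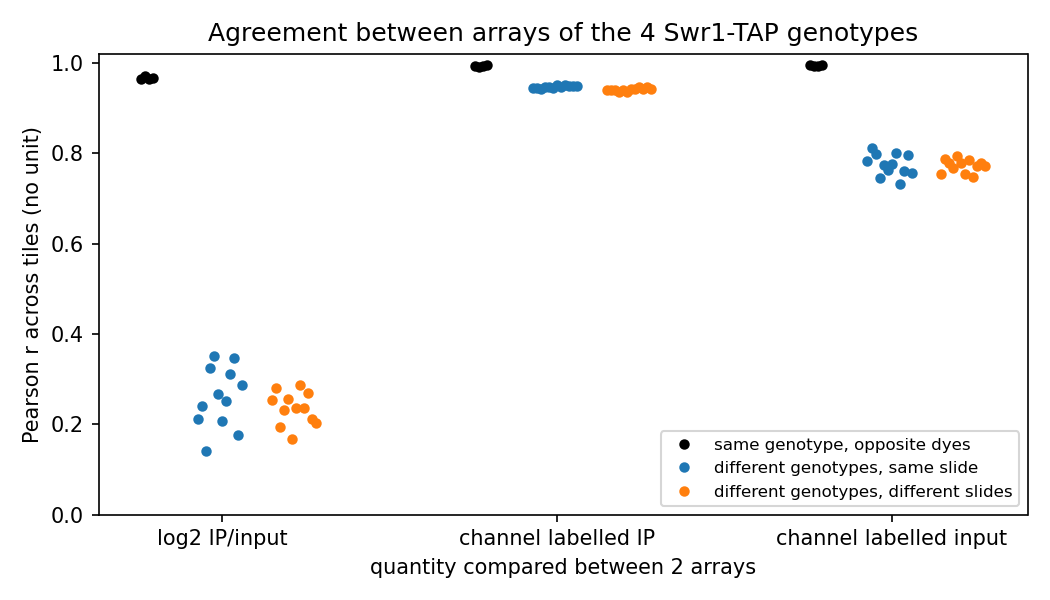
Pearson r across 4378 tiles (vertical axis, no unit) for every pair of arrays, for log2 IP/input, the channel labelled IP and the channel labelled input, where each point is 1 pair of arrays, coloured by whether the genotype and slide were shared. Dye-swapped arrays of 1 genotype reach 0.964 or more in all 3 quantities, whereas different genotypes reach at most 0.350 in the ratio.

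Loss of Swc2 addresses the part of SWR1 recruitment that runs through this subunit. In the arrays labelled swc2∆, 1241 tiles (28.3%) were lower than in WT and 1120 (25.6%) were higher by 1.5-fold on both orientations. The median over all tiles differed from WT by -0.024, a value that centring each array on its own median holds near 0. Over the 991 WT-bound tiles the median change was -0.88, with -0.83 on the first slide and -0.91 on the dye swap, and 822 of these tiles were below 0. Over the 1049 tiles bound in swc2∆ the median change was 0.85, and 856 were above 0. The lowest change, at tile CHG_P01117140, was -4.17, from 1.59 in WT to -2.58 in swc2∆. Tile CHG_P01133200 had the highest, 3.45, from -1.80 to 1.66. The slides gave -3.89 and -4.45 for the first and 3.11 and 3.80 for the second, which shows technical spread only. Over the top 20% of tiles by the mean of the 4 genotypes the median change was 0.0009. In the deposited value table's assignment the change was -0.092 at CHG_P01117140 and -1.38 at CHG_P01133200. With normexp background correction the changes were -4.28 and 2.18, so the second was smaller.

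Deletion of *HTZ1*, which removes the histone variant that SWR1 deposits, gave counts of similar size. In htz1∆, 1145 tiles (26.2%) were lower than in WT and 1135 (25.9%) were higher. The WT-bound tiles had a median change of -0.81, with slide values of -0.80 and -0.86, and 800 of 991 were below 0. Over the 1092 tiles bound in htz1∆ the median change was 0.86. The lowest change, -3.74, was at tile CHG_P01044260, from 2.37 in WT to -1.37 in htz1∆, with -3.41 and -4.07 on the slides. Tile CHG_P01130800 had the highest change, 3.48, from -0.46 to 3.02, with 3.31 and 3.65 on the slides. In the value table's assignment these changes were -0.62 at CHG_P01044260 and 1.48 at CHG_P01130800. Over the top 20% of tiles by the mean of the 4 genotypes the median was 0.057.

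The double mutant asks what remains when both are absent. In swc2∆ htz1∆, 1202 tiles (27.5%) were lower than in WT and 1091 (24.9%) were higher. Its WT-bound tiles had a median change of -0.97, with slide values of -0.92 and -1.03, and 862 of 991 were below 0. The 987 tiles bound in the double mutant had a median change of 0.91. Over the top 20% of tiles by the mean of the 4 genotypes the median was -0.16. Simulated unchanged groups, with the spread between genotypes taken as noise, gave 1077 tiles lower and 1090 higher per comparison, against 1145 to 1241 lower and 1091 to 1135 higher in the 3 mutants. That spread includes any real effect, so the simulation sets no floor for one.

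**Figure D2:**
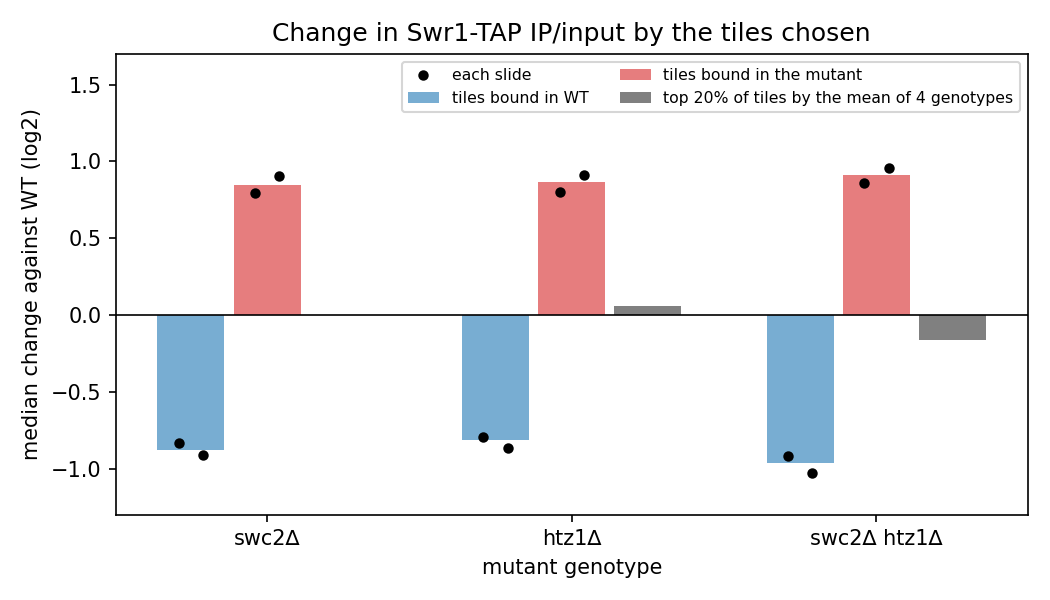
Median change in log2 IP/input against WT (vertical axis) for each mutant. Bars cover tiles bound in WT, tiles bound in the mutant, and the top 20% of tiles by the mean of the 4 genotypes. Each bar is the median over tiles of the change averaged over the 2 slides. Points are the medians on each slide, and the grey bars of the top 20% have none. Bars over WT-bound tiles lie at -0.81 or below and those over mutant-bound tiles at 0.85 or above, while the grey bars lie between -0.16 and 0.057.

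Against the single mutants, the double mutant had 1129 tiles lower and 1189 higher than swc2∆, and 1213 lower and 1099 higher than htz1∆. Over WT-bound tiles its median change was -0.11 from swc2∆ and -0.16 from htz1∆, with slide values of -0.12 and -0.12 for the first and -0.15 and -0.16 for the second. Over tiles bound in the single mutant itself the median change was -0.88 from swc2∆ and -0.97 from htz1∆. The interaction, which is the double mutant minus both single mutants plus WT, had a median of 0.74 over WT-bound tiles, with 0.71 and 0.77 on the slides. Over all tiles it was 0.045, where centring each array favours a value near 0. The WT-bound value turned to -0.24 over the top 20% of tiles by the mean of the 4 genotypes. Because WT enters the interaction with a plus sign, choosing tiles high in WT by itself favours a positive value. The 0.74 alone is therefore no evidence that the deletions interact.

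Comparisons of 1 deletion on the 2 backgrounds shared no array and were added after seeing the data. Across tiles, the change from deleting *SWC2* in the presence of *HTZ1* correlated with its change in the absence of *HTZ1* with r = 0.0834 and rho = 0.0740. The corresponding values for deleting *HTZ1* with and without *SWC2* were r = 0.0215 and rho = 0.0183. Deleting *SWC2* lowered 385 tiles on both backgrounds, where independent lists would share 344, and raised 326, against 281. The remaining pairing of the same profiles, the double mutant against WT with htz1∆ against swc2∆, gave r = -0.0621. There 279 tiles were lower in both against 309 for independent lists, and 312 were higher against 317. Each contrast of that pairing involves both deletions. By construction its covariance equals the *HTZ1* covariance minus the *SWC2* covariance, so it is no reference for either. For *HTZ1*, 295 tiles were lower on both, against 295 for independent lists, and 323 were higher, against 308. The 4 tiles named above were chosen as extremes on the first background, which by itself favours smaller values on the second. Deleting *SWC2* in htz1∆ changed CHG_P01117140 by 0.056 and CHG_P01133200 by 1.31. Deleting *HTZ1* in swc2∆ changed CHG_P01044260 by 0.61 and CHG_P01130800 by -1.43. With the sign turned, these are the same contrasts as those of the value table's assignment above, which differ slightly through the outlier marks used there.

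Changes against WT were correlated between mutants, and all of them shared the WT arrays. Pearson r was 0.450 for swc2∆ with htz1∆, 0.526 for swc2∆ with the double mutant and 0.478 for htz1∆ with the double mutant. Simulated unchanged groups gave 0.500 with the orientation spread alone and 0.498 with the spread between genotypes taken as noise. The observed covariances of 0.493, 0.587 and 0.516 compare with simulated covariances of 0.0184 and 0.572, respectively. Taking the changes from different slides gave r of 0.447, 0.521 and 0.474. Lower in both swc2∆ and htz1∆ were 622 tiles, against 325 for independent lists and 509 in the second simulation. Higher in both were 489 tiles, against 290 and 521. For swc2∆ with the double mutant, 671 tiles were lower in both and 540 higher, against 341 and 279 for independent lists. For htz1∆ with the double mutant the counts were 592 and 519, against 314 and 283. The second simulation, with no shared effect, gave 509 lower and 521 higher in both. Observed covariances minus that simulation's were -0.079 for swc2∆ with htz1∆, 0.015 for swc2∆ with the double mutant and -0.057 for htz1∆ with the double mutant. The spread simulated there includes any real effect, so differences near 0 cannot show that a shared effect is absent. WT was a single sample and could not be divided, so part or all of any excess over independent lists may come from the shared WT arrays.

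Differences between genotypes lay mostly in the channel labelled input. Over tiles, that channel correlated between genotypes with r from 0.732 to 0.813, and the channel labelled IP with r from 0.936 to 0.952. The SD between genotypes was 0.67 in the channel labelled input and 0.33 in the channel labelled IP. Corresponding SDs between dye orientations were 0.11 and 0.13. For the ratio, the SD between genotypes was 0.75, which is 3.90 times the SD of 0.19 between orientations.

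Tiles called bound by the labelled ratio were spread over the whole array. In WT, 24.1% of the 1448 tiles of the longest run, 22.3% of the 1234 tiles of the next and 21.8% of the 1406 CHG tiles elsewhere were bound. Of the 290 CEN tiles, 21.0% were bound in WT, 19.0% in swc2∆, 31.4% in htz1∆ and 19.0% in the double mutant. The median change of the CEN tiles against WT was -0.12 in swc2∆, 0.093 in htz1∆ and -0.088 in the double mutant. In the longest run, 31.0% of tiles were lower and 22.5% higher in swc2∆, whereas in the second longest run 26.4% were lower and 29.4% higher. With the ratio turned, 16.5% of tiles would be bound in WT in the longest run, 19.0% in the next and 18.2% elsewhere. Lower and higher would trade places in both runs, and the bound shares of CEN tiles would be 14.1% in WT, 18.6% in swc2∆, 18.3% in htz1∆ and 15.9% in the double mutant.

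The 10 isolated CEN runs shared 1 feature in all genotypes. Over the 40 serial numbers at the middle of these runs, signal minus that of the flanks was -4.15 to -3.81 log2 units in the channel labelled IP and -4.06 to -3.86 in the channel labelled input, as means over runs per genotype. The ratio at the middle minus that of the flanks had genotype means from -0.23 to 0.24. Single runs varied around these means with an SD of 0.69 to 1.01. Outside these runs, 91 short stretches had a running median of signal, averaged over arrays and channels, below -4 on the log2 scale. In 76 of them the mean was below -4 in each channel of each genotype, with a median length of 13.5 serial numbers. The longest, of 168 and 161 serial numbers, lay in the longest run at mean log2 signals of -7.78 and -7.02, and were at -6.95 or below in each of the 4 genotypes.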

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

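Tests in this part were chosen after the results were seen, with exceptions. The prediction for dim signal was written before. The choices of tiles bound on the other slide and of top tiles by the mean of the genotypes were planned settings. Some tiles were lower with a gene deleted on 1 background and higher on the other, by 1.5-fold on both orientations. There were 550 such tiles for *SWC2*, where independent lists would give 622, and 583 for *HTZ1*, against 604. Such counts alone are no evidence of opposite effects. The difference was not tested, since each genotype was 1 sample. Among the named tiles, chosen as extremes against WT, CHG_P01044260 was lower in htz1∆ than in WT on both slides, whereas the double mutant exceeded swc2∆ there by 0.61. CHG_P01130800 was higher in htz1∆ than in WT on both slides, whereas the double mutant minus swc2∆ was -1.43.

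The genotypes differed mainly in the channel that the labels call input, although genomic DNA of 4 nearly isogenic strains has little reason to differ. Additive deletion effects are argued against as the main source of these differences, because the higher of the 2 correlations of a deletion's changes between backgrounds was 0.0834. Dim signal is argued against too: over the brighter 50% of tiles the SD between genotypes in that channel was 0.62, above the 0.33 of the channel labelled IP over all tiles. The mean correlation between genotypes was higher by 0.172 in the channel labelled IP, which restates the pattern and is no test of an exchange of IP and input dyes in the labels. The exchange stays open, together with variation of single preparations and interacting effects of the deletions, which were not tested.

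WT-bound tiles had lower medians in swc2∆, htz1∆ and the double mutant than in WT, and the mirror-image rise over mutant-bound tiles had nearly the same size. Noise of the slide used for the choice is argued against, since over tiles bound on the other slide the medians were -0.81, -0.74 and -0.90. Over the top 20% of tiles by the mean of the 4 genotypes, the larger of the 2 single-mutant medians was 0.057, in htz1∆, and the double mutant's was -0.16. These last values cannot tell selection from movement, because binding that moved to other tiles in like amount also leaves such a set near 0. A loss with no gain elsewhere would put its median below 0. It was not below 0 in swc2∆ or htz1∆, and was in the double mutant. Selection on variation of the WT preparation and real movement of binding cannot be told apart with 1 preparation per genotype.

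The deposited value table was outside the main measurement, and all 8 of its columns equalled the scanner file of another sample. If the scanner labels were right and *HTZ1* were on the array, a stretch should be lost in the arrays labelled htz1∆ and swc2∆ htz1∆ alone, and the largest such loss was 2.37. If the table were right, the loss should fall in the arrays labelled swc2∆ and WT, where the largest was 1.41. For *SWC2* the largest loss was 1.23 in the arrays labelled swc2∆ and swc2∆ htz1∆, as the scanner labels would have it. It was 1.92 in those labelled htz1∆ and WT, as the table would have it. Pairs that match neither assignment gave 1.71 (WT with swc2∆ htz1∆) and 1.78 (swc2∆ with htz1∆). Losses of this size therefore point to neither assignment. All of these lie far from the 4 log2 units looked for, and no probe of either deleted gene was identified. The 2 assignments therefore cannot be told apart. A mislabelled set of scanner files and a mislabelled table are both possible.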

How the results depend on the processing

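The tile sizes and the exchanged dyes were chosen after seeing the data; the other settings were planned. Of 493 values under 22 alternatives, 351 kept their size within the spread of the 2 slides, or within 1.5 times for shares of tiles. Another 128 kept their sign but moved by more than that, towards 0 or away from it, and 14 changed sign. Unless a cause is stated, the cause was not tested. Medians over WT-bound tiles are listed for swc2∆, htz1∆ and the double mutant against WT, the double mutant against swc2∆ and against htz1∆, and the interaction. They reversed in swc2∆, htz1∆ and the interaction when tiles were chosen alike on all genotypes: the list read 0.026, 0.086, -0.069, -0.054, -0.068 and -0.099 over tiles bound in any genotype, and 0.0009, 0.057, -0.16, -0.21, -0.19 and -0.24 over the top 20% of tiles by the mean of the genotypes. By construction these sets do not favour WT over the mutants. They read -0.81, -0.74, -0.90, -0.10, -0.14 and 0.66 with bound tiles taken from the other slide, -0.96, -0.94, -1.09, -0.17, -0.20 and 0.77 with bound meaning the top 20%, and -1.08, -1.04, -1.22, -0.15, -0.21 and 0.88 at 2-fold. Further lists were -0.94, -0.87, -1.04, -0.11, -0.18 and 0.76 with probe medians, -0.93, -0.88, -1.06, -0.094, -0.16 and 0.78 with tiles of 10 serial numbers and -0.68, -0.66, -0.81, -0.10, -0.24 and 0.51 with tiles of 40. Normexp gave -0.86, -0.85, -0.96, -0.13, -0.095 and 0.76, loess -0.89, -0.82, -0.97, -0.11, -0.13 and 0.77, quantile scaling -0.87, -0.84, -0.95, -0.12, -0.11 and 0.77, scaling to 1 SD -0.90, -0.84, -0.98, -0.11, -0.13 and 0.79, and probes well above background -0.91, -0.81, -0.97, -0.10, -0.16 and 0.74. The deposited value table gave -0.86, -0.86, -0.92, -0.074, -0.11 and 0.75, exchanged dyes -0.81, -0.81, -0.86, -0.073, -0.040 and 0.80, and both together -0.84, -0.73, -0.89, -0.040, -0.17 and 0.65. Without either replicate in turn the lists ran from -0.82 to -0.79, -0.76 to -0.73, -0.91 to -0.89, -0.12 to -0.087, -0.17 to -0.13 and 0.64 to 0.67. With 1 slide left, the correlation of a deletion's changes between backgrounds was 0.0212 to 0.0224 for *HTZ1*. That correlation for *HTZ1* was 0.0140 with normexp, 0.0141 with loess, 0.0264 with quantile scaling, 0.0251 with SD scaling, 0.0164 with probe medians, 0.0172 with probes well above background, 0.0203 with at least 5 probes, 0.0205 with tiles of 40, and 0.0243 in the value table, with or without exchanged dyes. For *SWC2* it was 0.0737 with normexp, 0.0875 with SD scaling, 0.0720 with probe medians and 0.0723 with tiles of 10. Asking for 2-fold left 11.8, 12.3, 12.9 and 10.96% of tiles bound in WT, swc2∆, htz1∆ and the double mutant; in the 5 comparisons 16.1, 14.8, 16.1, 13.8 and 16.0% were lower and 14.5, 15.1, 13.9, 14.7 and 14.1% higher. A limma fit to the 8 arrays with the slide as a block called 44.4, 42.5, 44.0, 43.1 and 43.8% lower and 41.8, 42.1, 41.0, 43.6 and 41.7% higher at a Benjamini-Hochberg adjusted p under 0.05, measuring only the spread between arrays of 1 immunoprecipitation. By construction, exchanged dyes turned the named tiles to 4.17 at CHG_P01117140, -3.45 at CHG_P01133200, 3.74 at CHG_P01044260 and -3.48 at CHG_P01130800. In the value table the changes were -0.092 at CHG_P01117140, -1.38 at CHG_P01133200, -0.62 at CHG_P01044260 and 1.48 at CHG_P01130800, and with dyes exchanged as well the changes at CHG_P01117140, CHG_P01133200, CHG_P01044260 and CHG_P01130800 were 0.092, 1.38, 0.62 and -1.48. Not run, for want of probe positions and sequences, were centring on coding probes, the promoter windows of 250 and 600 bp and the removal of probes matching the genome more than once. No paired analysis was possible because each genotype was 1 immunoprecipitation, which leaves no independent pairs; changes were taken within slides throughout. Signal over background limited little: 172712 of 177440 features were well above background in both channels on all arrays.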

Other observations

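The tests in this part were all chosen after results were seen, and the bounds for the comparison with convergent regions were written once its value was known. Earlier scans chose the origin and spacing of a map from the array values themselves. The first, on chromosomes III and VI, already gave low swc2∆ values upstream of start codons on chromosome III at a spacing close to the one used here. A wider scan over every chromosome did not single out these chromosomes. A hypothesis was then tested that serial numbers follow chromosome position, with the longest run on chromosome III and the next on chromosome VI. The map was fixed from stretches without probes, placed at the Ty2 genes of both chromosomes and at the mating type locus, which gave 10.15 bp per serial number. The silent mating loci, left out of the fit, then lay 208 and 427 bp from the nearest of 10 other stretches without probes in the longest run. Of 10000 random pairs of positions, 0.150% were as close, which goes with the hypothesis for the longest run. The next run was placed on chromosome VI by its Ty2 gene alone, with the spacing of the longest run, and this placement had no check. That share does not allow for the choice of anchors or for the earlier scans. Gene positions were those of assembly R64 and may be slightly displaced on the array's own build.

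On that map, log2 IP/input in the 300 bp upstream of start codons was set against the window from 300 to 800 bp inside 180 genes. These genes were pooled over both chromosomes, including the unchecked placement on VI. In the arrays labelled swc2∆ the upstream value minus the coding value was -0.55, which is -6.26 in SDs of 10000 random shifts of the genes. Because the first scan had shown the same tendency, this was not a blind test, and the shifts do not allow for it. The arrays labelled swc2∆ htz1∆, htz1∆ and WT gave -0.25, -0.18 and -0.11, or -3.37, -2.18 and -1.41 in SDs of shifts. None of the shifts was as low as the observed value in swc2∆ or the double mutant, and 1.67% were in htz1∆ and 7.83% in WT. The channel labelled IP had like upstream differences in all 4 genotypes, from -0.38 to -0.29. In the channel labelled input they were 0.21 in swc2∆, -0.035 in the double mutant, -0.18 in htz1∆ and -0.27 in WT. Each channel carries probe and sequence bias that the ratio removes in part. The swc2∆ ratio upstream minus that at 29 regions between convergent genes was -0.45, or -2.54 in SDs of shifts. The same difference was 0.061 in the double mutant, -0.19 in htz1∆ and -0.12 in WT, against shift SDs of 0.15, 0.17 and 0.16, each within 2 SDs of 0. These values cannot decide on a bias of all intergenic DNA, because convergent regions are no neutral reference. In swc2∆, upstream signal exceeded theirs by 1.20 log2 units in the channel labelled IP and 1.65 in that labelled input. The 300 bp windows there also reached into genes wherever the region was narrower.

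The swc2∆ value lay at -6.26 SDs for the labelled ratio. Relative to coding windows, DNA upstream of start codons was thus richer in those arrays' channel labelled input than in that labelled IP. That restates the ratio and is no test of its source. The double mutant's ratio, at -3.37 SDs, goes the same way, but did not differ from convergent regions beyond the shifts. A bias of intergenic DNA stays open for both genotypes. Whether the dyes were exchanged stays open too.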
